A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

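RNA was measured in 12 libraries: 6 of RKO cells, a human colon cancer line, and 6 of mouse colon. The RKO cells carried an shRNA against ZNF280C behind a tetracycline-inducible promoter and were kept with 1 ug/ml doxycycline or without it for 72 h, with 3 libraries each. The mouse libraries came from the colon of 12-week-old C57BL/6J animals, 3 Zfp280c knock-out and 3 wild-type. Per the labels, polyadenylated RNA was selected, fragmented, primed with random hexamers and made into circularised libraries.

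The submitters' processing notes name HISAT, Bowtie2, HTSeq and edgeR and the build hg19, without versions, roles or order. They give no mouse build. The RKO table's file name says FPKM after ComBat, a batch adjustment, but its values contradict that unit: each column sums to between 9050161 and 9195211, against at most 507206.3 for the mouse FPKM, and the values increased with transcript length (Spearman 0.290 across 13141 genes, which are not independent replicates). In 8736 genes shared with the mouse table, that correlation was 0.141 for the RKO values and -0.223 for the mouse FPKM. The deposited RKO values are therefore called signal here, on the scale of normalized read counts after the authors' batch adjustment, whose batches and model are not given. The test had been fixed for FPKM before the data were examined and was kept as written. The mouse table holds FPKM per the file headers, printed to 2 decimals, for 17383 genes. The RKO table holds 15590 genes, 8 symbols that occur more than once and 2 unnamed empty columns. No per-sample column was left unused. Read depth is unknown for both tables, so no counting interval can be given.

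Each table was analysed on its own, since the tables were normalized separately. Values were taken as log2(value + 1), genes with a mean of at least 1 over the 6 libraries were kept (15590 in RKO, 11366 in colon), and groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with a trend in the variance). A gene passed, or was called, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The targeted gene was also compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. Errors are SD over 3 libraries for levels and SE for log2 fold changes.

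Gene lists for pathways, complexes and cell types were fixed before the data were examined, as were the tests, the naming rule and the alternatives except those described as added. Lists with at least 3 tested members (30 of 33 in RKO, 58 of 60 in colon) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of that comparison, and again with the correlation estimated from the data. Members were also counted after adjustment over the list alone. A list's median, mean and test differed in sign in 4 RKO lists and 10 colon lists, and 0 of these were called.

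Named genes were the targeted gene, H19 and IGF2, then in each direction the 10 genes with the largest change among called genes whose groups did not overlap. Places left open went to the lowest unadjusted p among groups that did not overlap. Of each list described, up to 4 members with the lowest unadjusted p were named. In 2 lists, 1 such gene is not reported here; the lists were tested with it. Other names are said to have been chosen after their values were seen. IGF2 in RKO cells and H19 in colon were not analysed here. Overlap between the comparisons was counted over same-symbol genes with Fisher's exact test.

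The alternatives were other pseudocounts, a lower and a higher minimum mean, 3 rescalings, robust variance estimation, the replicate number as a block, the estimated correlation and the removal of each library in turn. Added after the data were seen were a block of libraries that share exactly equal values, removal of the trend with GC content in each RKO library (lowess, span 0.3), the same genes without that correction, and a colon position score as a covariate. In that block, doxycycline replicate 1 and untreated replicate 3, which share 0 equal values, were paired because they were left over. GC content came from the longest GENCODE transcript of each symbol. Of the 15590 RKO genes, 12539 matched by symbol and 602 through a synonym, 84.3% in all. The position score was the mean log2 of Hoxb6, Hoxb7 and Hoxb8 minus that of 5 distal HOX genes. No genomic positions are given, because the annotation at hand follows another build than the tables.

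The procedure was tested on simulated data shaped like each table, with 200 changed genes and 10 repeats. In the RKO design it recovered 29.5% of changes of 0.3 on the log2 scale, 63.5% of 0.5 and 91.7% of 1, with at most 4.43% false calls. In the colon design it recovered 0% at 0.3 and 0.5 and 73.9% at 1, with 5.26% false calls. A list of 30 genes shifted by 0.3 was called in 10 of 10 runs in each design, and 0 of 200 unshifted lists were. The noise was drawn separately for each gene, so members of simulated lists were not correlated. Real lists were, with estimated correlations such as 0.389 for G2 and mitosis in RKO cells and 0.697 for interferon-stimulated genes in colon. The simulation therefore does not show how often such lists are called falsely at the preset correlation. The noise was also drawn separately for each library. In the RKO table, deviations within the equal-value pairs and the pair left over correlated negatively (mean -0.38). The share of false calls simulated for RKO genes therefore need not hold for the deposited values. Plots and tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.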

Results

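Expression was compared in 2 settings with 3 libraries per group: RKO colon cancer cells with and without induction of an shRNA against ZNF280C, and colon of Zfp280c knock-out and wild-type mice. Signal per RKO library summed to between 9050161 and 9195211 over 15590 genes. FPKM per mouse library summed to between 491900.5 and 507206.3 over 17383 genes.

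In RKO cells, the comparison asked which transcripts differ once the shRNA is switched on by doxycycline. ZNF280C, which encodes a zinc finger protein, fell to 51.0% of its level without doxycycline. Cell division, DNA replication and glycolysis genes were lower by small amounts, with TPX2, CCNA2, TYMS, PGK1 and LDHA among those that fell, and the mitochondrially encoded transcripts were higher. As lists they were called at the preset correlation only (adjusted p = 0.277, 0.277, 0.277 and 0.288 with an estimated correlation), and 6 of 40, 3 of 40, 4 of 34 and 1 of 13 of their genes passed. ZNF280C signal was 101 ± 22.1 with doxycycline and 197 ± 27.5 without (SD, n = 3 each), a log2 fold change of -0.98 ± 0.15 (adjusted p = 0.0276, limma). All 3 treated libraries lay below all 3 untreated ones (exact permutation p = 0.1, the smallest this design allows). The call ended in 5 of the 6 fits that left out 1 library: doxycycline replicate 2 (adjusted p = 0.0621) or 3 (0.0633), or untreated replicate 1 (0.0733), 2 (0.0892) or 3 (0.0922). The log2 fold change stayed between -1.13 and -0.82 in these fits.

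**Figure D1:**
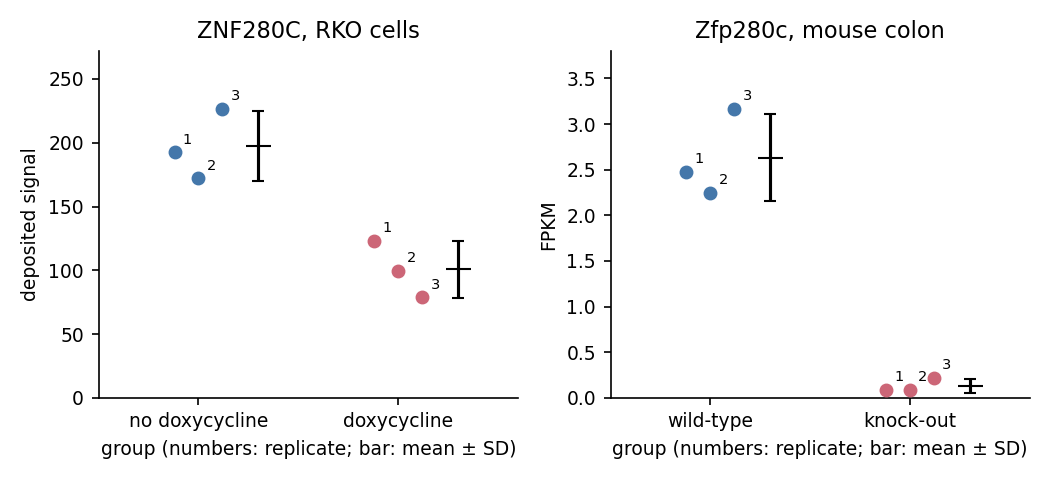
Level of the targeted gene in each library, as signal for ZNF280C in RKO cells (left) and FPKM for Zfp280c in mouse colon (right), with points numbered by replicate and bars showing mean ± SD of 3 libraries. Knocked-down cells averaged 101 against 197, and knock-out colon averaged 0.133 against 2.63, with no overlap between groups in either panel.

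Of 15590 genes, 60 rose and 118 fell with doxycycline, and in all 178 the 3 treated libraries lay on one side of the 3 untreated ones. Over all genes, 21.95% showed such a separation, against 10% for exchangeable libraries. The authors' batch adjustment may not have left the libraries exchangeable, so the 10% is no chance level for this grouping. The changes were small: their median size was 0.27 on the log2 scale and 0 genes changed more than 2-fold. Among the genes that rose most were LAMC3, a laminin chain (0.92 ± 0.18, adjusted p = 0.0459), TMEM63C (0.78), C19orf33 (0.76), the netrin receptor UNC5A (0.73), the mitochondrial methionine tRNA MT-TM (0.69), ACTA2-AS1 (0.67), the cytokine signalling inhibitor SOCS1 (0.65), CTD-2571L23.6 (0.64), the kinase RPS6KA2 (0.62) and the dynein chain DNAH1 (0.60). After ZNF280C, those that fell most were WISP3 (-0.67), the peptide hormone ADM (-0.53), the mTORC1 inhibitor DDIT4 (-0.52), RP11-442H21.2 (-0.52), FITM2 (-0.50), JDP2 (-0.50), HMGB2 (-0.46), the linker histone HIST1H1C (-0.45) and MZT1 (-0.43). HMGB2, a chromatin protein gene, had the lowest adjusted p, 0.00119, at 1702 ± 35.2 against 2344 ± 44.6 signal.

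These counts depended on single libraries, on scaling and on how libraries that share exactly equal values were treated. Blocking on those pairs and on the pair left over, which shares 0 equal values, was added after the data were seen. In that fit 0 genes passed in limma (1670 at an unadjusted p under 0.05), and ZNF280C did not (adjusted p = 0.0769). Without doxycycline replicate 1, 2 or 3, the fit called 24, 17 and 1 genes. Without untreated replicate 1, 2 or 3, it called 3, 1 and 1. HMGB2 was called in each of the 4 smallest sets, joined by PSD4 and STMN1 without untreated replicate 1, names chosen after their values were seen. With all libraries scaled to the same sum, 56 rose and 66 fell. Quantile normalization gave 69 and 62 and median centring 72 and 59, so the excess of lower genes was reversed by the last pair. Every 1 of the 178 genes kept its sign in all of these fits. Leaving out 1 library could not turn a sign, since the groups do not overlap in these genes. The block could not either, since it leaves log2 fold changes as they are. The kept signs in those fits therefore say nothing about robustness.

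A trend with GC content ran through the RKO comparison. Across 13141 genes, which are not independent replicates, log2 fold change correlated with transcript GC content (Spearman 0.44) and hardly with length (-0.013). Median GC content was 60.8% in genes that rose, 41.0% in genes that fell and 48.3% overall. On these genes alone, 73 rose and 141 fell without a correction, and 30 rose and 58 fell with the trend removed. Of those 88, 68 were also called in the test over all 15590 genes. ZNF280C then stood at -0.90 ± 0.14 (adjusted p = 0.0383, limma).

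**Figure D2:**
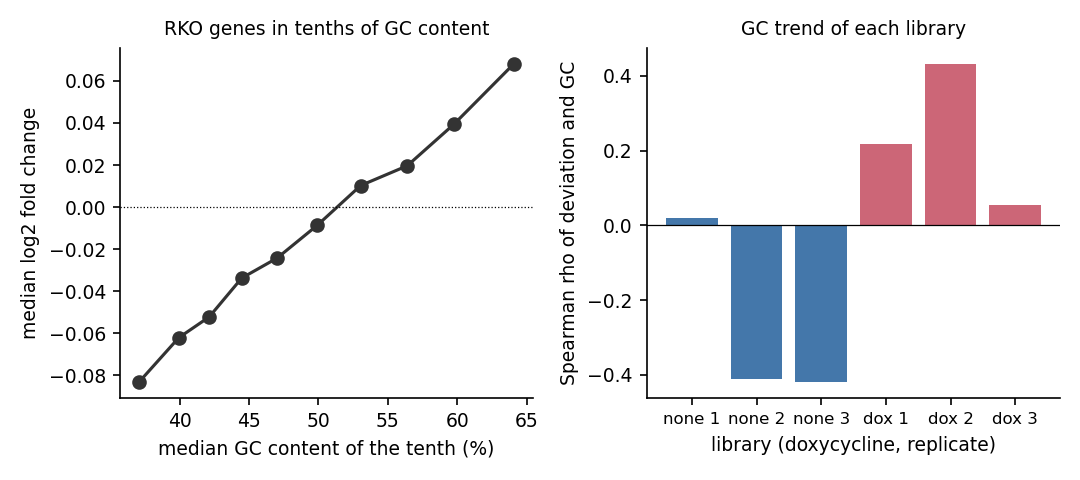
Left, median log2 fold change with doxycycline in 10 equal bins of RKO genes ordered by GC content (%), from -0.083 to 0.068. Right, Spearman correlation of each library's deviation from the mean with GC content, from -0.419 in untreated replicate 3 to 0.433 in doxycycline replicate 2. It was weakest in untreated replicate 1 (0.019) and doxycycline replicate 3 (0.055).

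Cell division and DNA replication made up the lists with the lowest p, and repair genes were lower too. All 40 G2 and mitosis genes had negative log2 fold changes (median -0.17). Of these, 6 fell over all genes and 29 when adjusted over the list alone, among them the spindle assembly factor TPX2 (-0.25, adjusted p = 0.0152), cyclin A2, CCNA2 (-0.25), securin, PTTG1 (-0.21), and the kinetochore gene NDC80 (-0.36). Of the 40 DNA replication and S phase genes, 39 were negative (median -0.13), 3 fell and 23 fell when adjusted over the list alone. The 3 were thymidylate synthase, TYMS (-0.24), DNA polymerase alpha, POLA1 (-0.26), and the helicase factor CDC45 (-0.27), while PRIM1 did not pass (-0.25, adjusted p = 0.0502). Of the 35 homologous recombination and DNA repair genes, 31 were negative (median -0.09). In that group EXO1 fell (-0.25), 9 fell when adjusted over the list alone, and MSH6 (-0.13), BARD1 (-0.19) and CHEK1 (-0.19) did not pass over all genes. All 3 lists were called lower at the preset correlation (adjusted p = 1.43e-20, 8.06e-14 and 3.19e-05). With an estimated correlation none was, at adjusted p = 0.277, 0.277 and 0.408. With the GC trend removed, their medians were -0.14, -0.12 and -0.05, all still called at the preset correlation.

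Of the 34 glycolysis and hypoxia genes, 31 were negative (median -0.21), 4 fell and 23 fell when adjusted over the list alone. PGK1 (-0.32) and LDHA (-0.26) encode glycolytic enzymes, PDK1 (-0.26) an inhibitor of pyruvate dehydrogenase, and ADM is the fourth. CA9, named after its values were seen, stood at -1.58 without passing (adjusted p = 0.215), with 16.8 signal in doxycycline replicate 1 and 130 and 122 in the others. The list was called lower at the preset correlation (adjusted p = 6.90e-13; adjusted p = 0.277 with an estimated correlation). Of the 30 ATF4 and amino acid stress genes, 25 were negative (median -0.17) and DDIT4 fell, the only member that passed also when adjusted over the list alone. PSAT1 (-0.42), SLC3A2 (-0.31) and MTHFD2 (-0.32) did not pass. That list was called lower (adjusted p = 0.00283; adjusted p = 0.630 with an estimated correlation), but not without doxycycline replicate 2, where its median was 0.00450 (adjusted p = 0.607), or untreated replicate 2 (-0.0748, 0.168). All 13 mitochondrially encoded mRNAs were positive (median 0.13; 0.18 with the GC trend removed). MT-ND1, a complex I subunit, rose (0.22, adjusted p = 0.0490), 6 rose when adjusted over the list alone, and MT-ND3 (0.17), MT-ATP6 (0.28) and MT-ND2 (0.16) did not pass over all genes. The mitochondrial list was called higher (adjusted p = 1.38e-06; adjusted p = 0.288 with an estimated correlation).

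Among chromatin regulators, all 15 cohesin and CTCF genes were negative (median -0.14, and -0.07 with the GC trend removed). Of these, 0 passed in limma over all genes, 10 had an unadjusted p under 0.05, and the same 10 fell when adjusted over the list alone. CDCA5 stood at -0.21, the cohesin subunit RAD21 at -0.17, CTCF at -0.14 and ESCO2 at -0.18. The list was called lower (adjusted p = 2.30e-07; adjusted p = 0.277 with an estimated correlation). EZH2, the methyltransferase of Polycomb repressive complex 2, fell (-0.25, adjusted p = 0.0335). It was the only 1 of 28 Polycomb genes that passed, over all genes or over the list alone, and PCGF5 (-0.19), PHC3 (-0.14) and CBX7 (0.13) did not. The Polycomb list (median -0.07, 20 negative) was called lower at adjusted p = 0.0471 (adjusted p = 0.277 with an estimated correlation), but not without doxycycline replicate 1 (0.0906) or 2 (0.0596), without untreated replicate 2 (0.0687) or 3 (0.0611), under the 3 rescalings (0.0562 to 0.0939) or over the genes with a GC content, whether the GC trend was kept (0.0586) or removed (0.0529).

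H19, the imprinted non-coding RNA gene, showed no change that passed: 34.4 ± 11.2 signal with doxycycline and 32.2 ± 7.54 without (SD, n = 3 each), a log2 fold change of 0.06 ± 0.24 (adjusted p = 0.936, limma). Its sign turned without doxycycline replicate 2 (-0.07) or 3 (-0.10), without untreated replicate 1 (-0.12) and with the GC trend removed (-0.00598). Of 10 genes around H19 and IGF2, 8 were positive (median 0.08) and SLC22A18 rose (0.44, adjusted p = 0.0487), the only member that passed over all genes or over the list alone. PHLDA2 (0.11), CDKN1C (0.19) and MRPL23 (-0.07) did not pass. The list was called higher (adjusted p = 0.0254; adjusted p = 0.344 with an estimated correlation). It was not called without doxycycline replicate 3 (0.0969) or with the GC trend removed, where its median was 0.00627 (adjusted p = 0.763).

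Of 18 Wnt/beta-catenin targets, 15 were positive (median 0.08). The ephrin receptor EPHB2 rose (0.27, adjusted p = 0.0397), 2 rose when adjusted over the list alone, and SOX9 (0.38), TCF7 (0.15) and NKD2 (0.16) did not pass over all genes. The list was called higher (adjusted p = 0.000351; adjusted p = 0.277 with an estimated correlation). Of 14 TGF-beta targets, 11 were positive (median 0.04), 0 passed in limma, 5 had an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. ID1 (0.33), LTBP2 (0.13) and BHLHE40 (-0.10) were among those with the lowest unadjusted p. That list was called higher at adjusted p = 0.0493 (adjusted p = 0.388 with an estimated correlation), but not without doxycycline replicate 1 (0.0570) or 2 (0.202), without untreated replicate 2 (0.177), with equal sums (0.0543) or median centring (0.0523), or over the genes with a GC content, whether the GC trend was kept (0.0531) or removed (0.124).

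**Figure D3:**
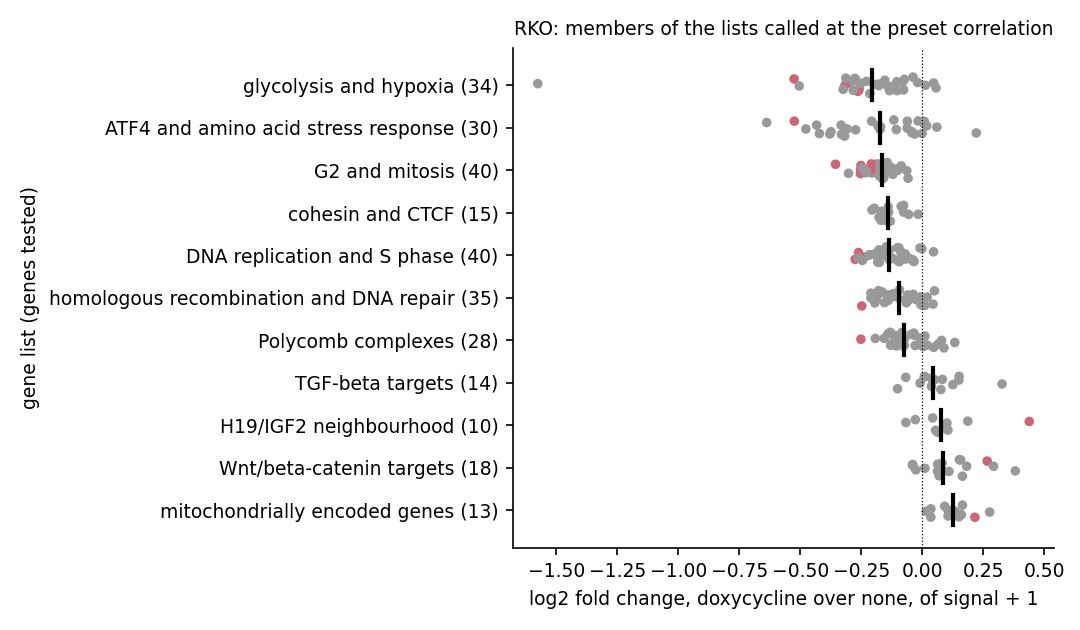
Log2 fold change with doxycycline of each member of the 11 gene lists called at the preset correlation, with red points for genes past the threshold over all genes and black bars for list medians. Medians run from -0.21 for glycolysis and hypoxia to 0.13 for mitochondrially encoded genes, and CA9 lies apart at -1.58.

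In mouse colon, the comparison asked which transcripts differ when Zfp280c is deleted. Zfp280c was nearly lost from knock-out colon, and interferon-stimulated, adipocyte and fatty acid oxidation genes had higher group means there. By list mean, wild-type replicate 2 lay near the knock-outs for interferon-stimulated and fatty acid oxidation genes. For adipocyte genes it lay between the other wild-types and the knock-outs. In limma 0 of 11366 genes passed, with 1420 at an unadjusted p under 0.05. Zfp280c (Entrez gene 208968) stood at 0.09, 0.09 and 0.22 FPKM in knock-out and 2.48, 2.25 and 3.17 in wild-type libraries. Its mean was 0.133 ± 0.0751 against 2.63 ± 0.479 (SD, n = 3 each), 5.06% of wild-type, with the lowest p of all genes (log2 fold change -1.67 ± 0.14, adjusted p = 0.123, limma). The added 1 FPKM shrinks this fold change, which was -3.58 with 0.1 added. The groups did not overlap (exact permutation p = 0.1, the smallest possible).

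The knock-out libraries carried more proximal and less distal HOX RNA than 2 of the wild-type libraries, at genes named after their values were seen. HOX genes mark position along the gut. Hoxb6 stood at 18.24, 8.91 and 17.63 FPKM in knock-out and 0.65, 18.23 and 0.20 in wild-type libraries. Hoxb13, a distal gene, stood at 2.23, 12.9 and 18.89 in knock-out and 336.32, 14.72 and 506.98 in wild-type libraries. Hoxb7 and Hoxb8 followed Hoxb6, and Hoxd13 reached 68.45 in wild-type replicate 3 and at most 0.96 elsewhere. The first principal component, with 77.7% of the variance, put wild-type replicate 2 at -17.7 with the knock-outs (-25.4, -19.2 and -18.0), and wild-type replicates 1 and 3 at 28.9 and 51.4. Without wild-type replicate 2, 1045 genes were called higher and 816 lower of 11344, Zfp280c among the lower (adjusted p = 0.00205). With the position score as a covariate, 0 genes passed in limma and 421 had an unadjusted p under 0.05. The score was 0.599 to 2.02 in the knock-outs, 1.12 in wild-type replicate 2, and -3.25 and -5.02 in wild-type replicates 1 and 3. Group differences fitted with this covariate, here and below, therefore rest largely on wild-type replicate 2. Of 15 proximal colon genes, 12 were positive (median 1.34), with Cyp2c55 (1.22) and B4galnt2 (1.34) higher and the goblet cell product Zg16 (-0.89) and Slc37a2 (-4.02) lower. The list was called higher at the preset correlation (adjusted p = 0.00911; adjusted p = 0.822 with an estimated correlation), but not without knock-out replicate 2 (0.102) or with the position covariate (median -0.14, adjusted p = 0.852), whose score includes 3 of its 15 genes. In limma 0 of its genes passed, with 8 at an unadjusted p under 0.05. The distal colon list, with 9 of 15 negative, was not called (median -0.67, adjusted p = 0.409).

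**Figure D4:**
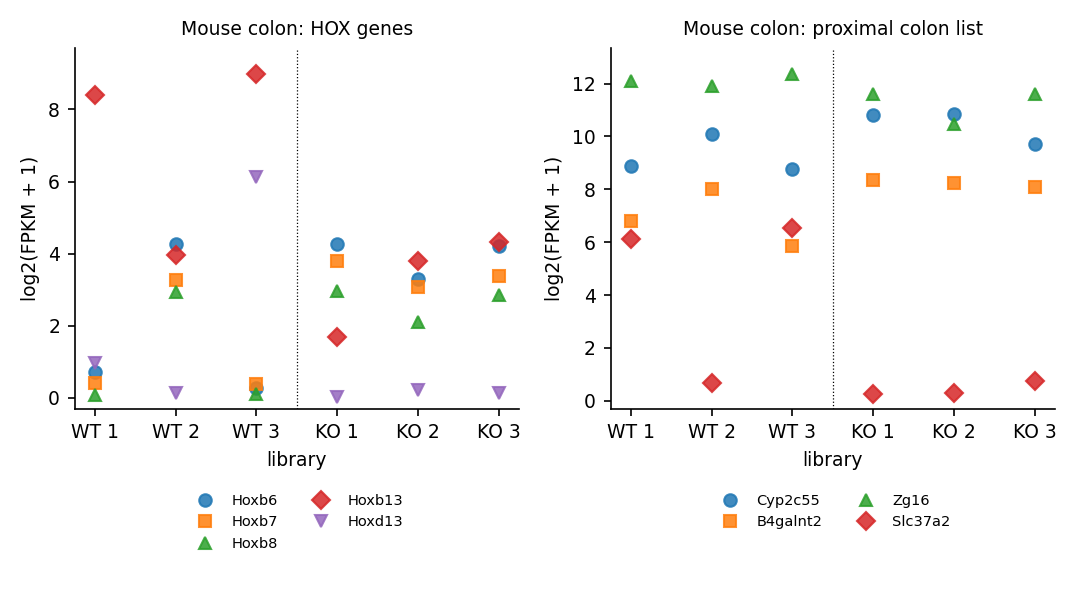
log2(FPKM + 1) of 5 HOX genes (left) and of 4 members of the proximal colon list (right) in each colon library, 1 symbol per gene, with wild-type (WT) left and knock-out (KO) right of the dotted line. Wild-type replicate 2, with Hoxb13 at 14.72 FPKM, lies with the knock-outs, while wild-type replicates 1 and 3 reach 336.32 and 506.98.

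In 16.9% of genes all 3 knock-out libraries lay on one side of all 3 wild-type ones, against 10% for exchangeable libraries. Genes varied together, with 77.7% of the variance in the first principal component, and the excess over 10% was not tested. The genes named here had the lowest p among the genes so separated, and none passed the threshold. Higher in knock-out colon were 5730507C01Rik, at 31.0 ± 1.66 against 8.03 ± 2.54 FPKM (SD, n = 3 each; adjusted p = 0.211, limma), Dtx3l, a ubiquitin ligase gene (28.5 against 11.1), 9030624G23Rik (5.16 against 1.43), Zfp809, a repressor of retroviral elements (13.4 against 7.60), Lrrc8b (7.79 against 2.21), Gm13251 (4.22 against 2.09), osteoglycin, Ogn (24.3 against 16.3), the cytochrome Cyp2e1 (6.99 against 0.820), 2410141K09Rik (1.94 against 0.793) and Gm11437 (7.31 against 3.74). Lower were Oit1 (569 against 800), Nxpe2 (8.78 against 22.0), Nrbp2 (9.12 against 14.2), Cd177 (18.7 against 30.1), the transcription factor genes Ovol2 (10.7 against 15.8) and Foxa2 (3.34 against 8.26), the copper chaperone Atox1 (65.4 against 84.5), Eif1b (11.8 against 15.4) and Gstm2 (42.9 against 57.8). Apart from 5730507C01Rik, these 19 genes had an adjusted p of 0.396 in limma. Without wild-type replicate 2, all of them passed. Igf2 stood between 0.32 and 0.86 FPKM, mean 0.653, below the minimum for testing.

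Interferon-stimulated genes formed the list with the lowest p: 30 of 31 were positive with a median of 1.07, 0 passed over all genes in limma (23 at an unadjusted p under 0.05), and 12 were higher and 1 lower when adjusted over the list alone. Dtx3l (1.30), the RNA sensor Ifih1 (0.50) and Parp9 (0.64) were higher, and Ifi27 was lower (-0.32). The list was called higher at the preset correlation (adjusted p = 6.86e-14; adjusted p = 0.822 with an estimated correlation). Its mean lay 1.31, 0.81 and 1.01 above the wild-type mean in the knock-outs, and at 0.79 in wild-type replicate 2, against -0.14 and -0.65 in wild-type replicates 1 and 3. Its median was 0.19 with the position score as a covariate, still called at the preset correlation. Of 17 T and NK cell markers, all were positive (median 0.56), with the granzymes Gzmb (1.55) and Gzma (1.48), Il2rb (0.39) and Cd3g (0.69), and 0 passed in limma over all genes or the list alone (5 at an unadjusted p under 0.05). All 15 macrophage and dendritic cell markers were negative (median -0.31), with Ms4a7 (-0.44), Cd14 (-0.53), lysozyme, Lyz2 (-0.77), and complement C1qa (-0.50), and 0 passed in limma in either count (2 at an unadjusted p under 0.05). Both lists were called (adjusted p = 1.05e-06 and 0.00306; adjusted p = 0.822 each with an estimated correlation), the macrophage list not without wild-type replicate 1 (0.113). With the position covariate neither was called (0.256 and 0.852). Wild-type replicate 2 lay with the knock-outs in both lists, at 0.56 and -0.32 from the wild-type mean.

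Adipocyte genes were higher in all 3 knock-out libraries than in any wild-type library as a list, with 12 of 13 positive and a median of 0.98. Cfd, the adipokine adipsin, averaged 33.9 ± 17.7 against 3.73 ± 3.34 FPKM (SD, n = 3 each), adiponectin, Adipoq, 5.76 against 0.507, the fatty acid binding protein Fabp4 30.7 against 6.22, and resistin, Retn, 1.91 against 0.470. Of these 13 genes, 0 passed in limma over all genes, 11 had an unadjusted p under 0.05 and 11 were higher when adjusted over the list alone, and the list was called (adjusted p = 4.45e-09; adjusted p = 0.822 with an estimated correlation). The list mean of wild-type replicate 2 lay at 0.48, between the other wild-types (-0.16 and -0.32) and the knock-outs (1.29, 0.77 and 1.37). Of 22 PPAR target and fatty acid oxidation genes, 21 were positive (median 0.39), with the mitochondrial enzymes Cpt2 (0.53), Cpt1a (0.48) and Hadha (0.39) and the peroxisomal Acaa1b (2.74). That list was called (adjusted p = 1.88e-08; adjusted p = 0.822 with an estimated correlation), with 0 members past the threshold in limma over all genes or the list alone and 11 at an unadjusted p under 0.05. Wild-type replicate 2 stood at 0.61 in it, within the knock-outs (0.77, 0.57 and 0.78).

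**Figure D5:**
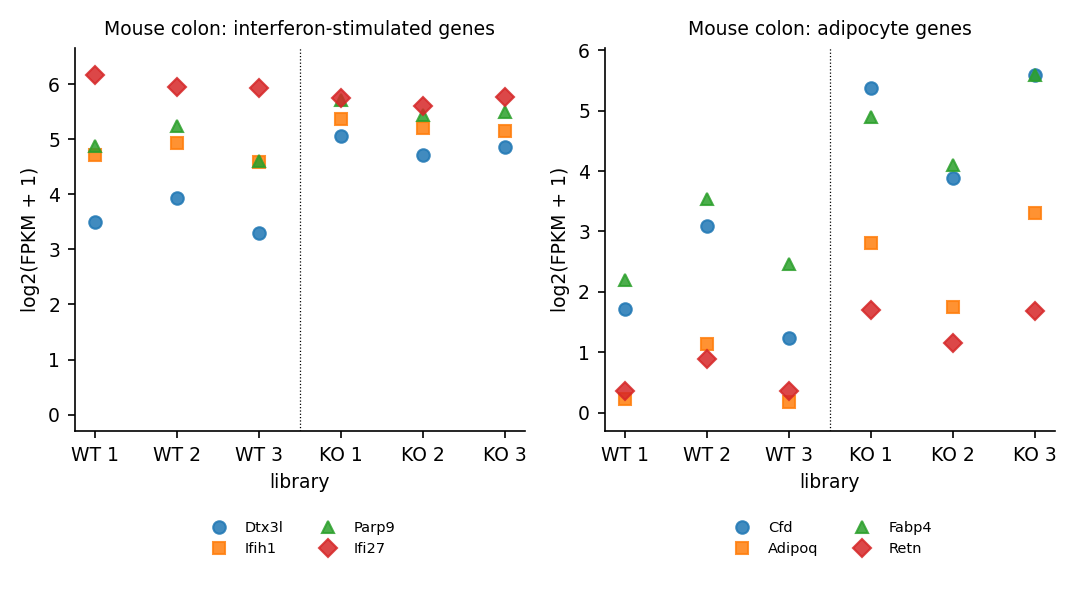
log2(FPKM + 1) of 4 interferon-stimulated genes (left) and 4 adipocyte genes (right) in each colon library, 1 symbol per gene, with wild-type (WT) left and knock-out (KO) right of the dotted line. Cfd averages 33.9 FPKM in knock-out and 3.73 in wild-type colon, and wild-type replicate 2 is the highest wild-type library for the 4 adipocyte genes.

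Lists of housekeeping processes were lower by small amounts. Of 42 nuclear oxidative phosphorylation genes, 40 were negative (median -0.14), with Ndufb10 (-0.33), Ndufs3 (-0.23), Ndufa8 (-0.25) and Sdhc (-0.24), and all 48 cytosolic ribosomal protein genes were negative (median -0.13), with Rps28 (-0.35), Rps6 (-0.27), Rpl9 (-0.43) and Rpl23 (-0.19). Both were called (adjusted p = 3.90e-07 and 3.72e-06; adjusted p = 0.822 each with an estimated correlation), the ribosomal list not after quantile normalization (median -0.03, adjusted p = 0.337). Of 30 G2 and mitosis genes, 28 were positive (median 0.46), with cyclin B1, Ccnb1 (0.78), Anln (0.50), Dlgap5 (0.36) and Kif23 (0.55). That list was called higher (adjusted p = 1.89e-05; adjusted p = 0.822 with an estimated correlation), but not with genes of a mean of at least 5 (0.105) or with the position covariate, where its median was -0.13. Of 18 smooth muscle markers, 17 were positive (median 0.38), with Mylk (0.66), Hspb7 (0.56), Myl9 (0.64) and Synpo2 (0.36), and the list was called (adjusted p = 2.35e-06; adjusted p = 0.822 with an estimated correlation). In these 4 lists 0 genes passed in limma over all genes or the list alone, with 9, 4, 0 and 5 at an unadjusted p under 0.05. Wild-type replicate 2 stood at 0.53 in the mitosis list and 0.33 in the smooth muscle list, above the other wild-types.

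The last comparison asked whether the genes that changed in RKO cells also differed in knock-out colon. Across 8751 genes tested in both, which are not independent replicates, log2 fold changes hardly correlated (Pearson 0.029, Spearman 0.027) and 53.4% had the same sign. Of 132 genes called in RKO cells, 74 (56.1%) had the same sign in colon. With 0 genes called in colon by limma, 0 could be shared, so Fisher's exact test decides nothing here. Neither the 38 higher nor the 94 lower RKO genes formed a called set in colon (camera adjusted p = 0.390 and 0.604, and 0.847 each with an estimated correlation). Without wild-type replicate 2, 3 genes were higher in both, CDX2, METTL7B and SLC22A18, where 2.84 would be shared by chance (exact p = 0.760), and 5 lower in both, AK3, DDIT4, HIST1H1C, PGK1 and PPP1CC, where 5.48 would be (exact p = 1). Matching by symbol leaves out genes named differently in the 2 species. ZNF280C and Zfp280c are such a pair and were called lower in their own comparisons, in colon in this fit.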

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

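All explanations weighed here were tested after the results had been seen, as were the choices of position score, GC correction and equal-value pairs.

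Of 28 lists tested in both comparisons, 4 had all 3 treated RKO libraries on one side of the control mean and all 3 knock-out libraries on the other side of the wild-type mean, 3 of them called in either, as did 2 named genes. Single libraries of the 2 groups overlap in each of these 3 lists, in RKO cells or in colon. The difference was not tested, because the tables were normalized separately. Other lists lay on the same side in both by this rule. Glycolysis and hypoxia, nuclear oxidative phosphorylation and mitochondrial translation were lower. Mesenchymal and matrix, TGF-beta and epithelial junction genes were higher, with TGF-beta targets called in both at the preset correlation. The lists of opposite sign therefore do not show that the 2 comparisons diverge as a whole. The mean log2 fold change of G2 and mitosis genes was -0.17 in RKO cells and 0.42 in colon. For the H19/IGF2 neighbourhood it was 0.10 and -0.0618, though the colon median was 0.0162 with 7 of 12 genes positive, and for xenobiotic and NRF2 targets -0.0709 and 0.37. ID1 stood at 0.33 in RKO cells and Id1 at -0.41 in colon, and BHLHE40 at -0.10 and Bhlhe40 at 0.26.

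In colon, wild-type replicate 2 lay with the 3 knock-outs. Over 1858 of the 1861 genes called without it, those tested also with it, its median place was 0.921, where 0 is the other wild-types and 1 the knock-outs (quartiles 0.779 to 1.05; 94.2% over 0.5), which argues against loss of Zfp280c as the source of most of those calls, since this library keeps the gene. It leaves open those nearer the wild-types, such as 5730507C01Rik (0.317) and Dtx3l (0.357). Zfp280c, the deleted gene itself, lay at 0.131. Its Zfp280c level of 2.25 FPKM, against at most 0.22 in knock-outs, argues against a mislabelled sample. The piece of colon sampled stays open: on the HOX position score its place was 0.985, but that score was chosen after these genes were seen, and its place lies within the quartiles of all these genes.

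Adipocyte genes were higher in knock-out colon. The piece of colon sampled stays open: with the position score as a covariate the list's median was 0.35, against 0.98 without it, and it was called at the preset correlation but not with an estimated correlation (adjusted p = 0.942). Fat tissue on the sampled pieces stays open too: the members' mean correlation within groups, 0.464, decides nothing, since 16 of the 58 colon lists had one as high. So does loss of Zfp280c, with an exact permutation p of 0.1, the smallest possible. These 3 cannot be told apart, because genotype, position score and list means differ together and no library measures fat on its own.

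In RKO cells, 178 genes were called, and exactly equal values occurred only between doxycycline replicate 2 and untreated replicate 2 (310 genes) and between doxycycline replicate 3 and untreated replicate 1 (526 genes). GC content as the whole cause is argued against, since 88 genes were still called after its removal, but it may account for the H19/IGF2 neighbourhood list, whose median was 0.00627 after its removal and 0.08 before. A batch adjustment stays open, with or without a group term: the 3 other splits that part those pairs and the pair left over called at most 0 genes, but had 1185 to 1819 at an unadjusted p under 0.05, against 149 to 720 in the 6 splits that do not and 2656 in the real split. Deviations within these pairs and the pair left over also correlated negatively (mean -0.38). Deviations sum to 0 within each group, so the positive mean of the other pairs (0.19) follows from this and is no baseline. Doxycycline itself cannot be told apart from loss of ZNF280C, because 0 libraries had doxycycline without this shRNA. Other effects of inducing this shRNA cannot be told apart either, since the labels name no other shRNA.

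Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. In RKO cells, 1 of the 10 splits called as many genes (178 in the real split, highest other 0) and 4 called as many lists (11, highest other 14). In colon, 4 of the 10 splits called as many lists (19, highest other 25). The count of genes called decides nothing there, since the real split called 0 and no split can call fewer. At an unadjusted p under 0.05 in limma, the real split had 1420 genes. Grouping wild-type replicate 2 with knock-out replicates 1 and 3 gave 2034, and with 1 and 2 gave 1248. The remaining splits had at most 488.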

How the results depend on the processing

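Chosen after the data were seen were the equal-value block, the GC correction, the genes with a GC content and the position covariate. Causes of the differences below were not tested. RKO counts of 60 higher and 118 lower genes stayed within a factor of 1.5 under other pseudocounts, minimum means and robust variance. Pseudocounts and a lower minimum could hardly change them. Library medians were 199.8 to 204.6 signal, and the lower minimum kept the same 15590 genes. Lower genes numbered 66 after scaling to equal sums, 62 after quantile normalization, 59 after median centring and 58 with the GC trend removed (30 higher). Leaving out 1 library gave 0 to 9 higher and 1 to 15 lower. The replicate block left 0 higher and 1 lower, HMGB2, with 2 residual degrees of freedom in place of 4. The labels do not say that replicate numbers pair samples. Deviations of same-number libraries correlated at 0.08, -0.53 and 0.06 in RKO and at -0.45, -0.14 and 0.15 in colon. These values do not decide it, since number 2 in RKO, at -0.53, is also an equal-value pair. The equal-value block, with the pair left over, left 0 and 0, with 1670 genes at an unadjusted p under 0.05 in limma. ZNF280C did not pass under either block (adjusted p = 0.0991 and 0.0769; neither can change its -0.98) and ranged from -1.13 to -0.82 with 1 library left out (adjusted p from 0.0229 to 0.0991 over all alternatives). H19 ranged from -0.12 to 0.36 with 1 library left out and was -0.00598 with the GC trend removed. With an estimated correlation 0 RKO and 0 colon lists were called, against 11 and 19. Other settings called 8 to 14 RKO lists and 14 to 23 colon lists.

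In colon, 0 genes passed in limma under every setting except without wild-type replicate 2, which gave 1045 higher and 816 lower (otherwise 0 with 1 library left out). Zfp280c ranged from -1.75, the one fit in which it passed, to -1.57 with 1 library left out, and had no value at a minimum mean of 5. With other pseudocounts it was -3.58 and -4.31, and with equal sums -2.29, none past the threshold. The overlap was 0 with any other library left out and 8 without wild-type replicate 2. With the position covariate, lists of G2 and mitosis (-0.13), tuft cells (-0.13), endothelium (0.0478) and enteric glia and neurons (-0.24) turned, as did Kif23 (-0.0617), Taldo1 (-0.0195), Matk (-0.15), Ccl21a (0.35), Mmrn1 (0.21), Stmn2 (-0.0688), Snap25 (-0.0595), Tac1 (-0.12) and Rbp2 (0.0932). Hoxb6 (-0.24), Hoxb8 (-0.18) and Hoxd13 (0.57) turned too, but they are part of the score, so their turn says little. The fit with this covariate rests largely on wild-type replicate 2. Medians of TGF-beta targets (-0.0489), mesenchymal and matrix genes (-0.0383) and proximal colon genes (-0.14, with 3 of the 15 in the score) were negative there too, without a call. Under the replicate block, mitochondrial translation (adjusted p = 0.0520) and TGF-beta targets (0.0530) were not called. Of the other values for named genes and lists, 2684 kept sign and side of the threshold, 351 no longer passed and 78 newly passed. Of the 2684, 1453 belonged to colon genes, which had not passed and so had no call to lose. RKO genes made up 291 of the 351, against 794 RKO gene values that stayed the same. Read depth is unknown and its limits cannot be given.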

Other observations

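Further colon lists were called at the preset correlation, each at adjusted p = 0.822 or above with an estimated correlation and with 0 members past the threshold in limma over all genes or the list alone. In the order described, 3, 0, 0, 1, 4, 3, 3, 2 and 2 members had an unadjusted p under 0.05. Small intestine genes were higher (8 of 10 positive, median 0.57, adjusted p = 0.0220), with Dmbt1 (0.66), sucrase-isomaltase, Sis (1.32), the bile acid transporter Slc10a2 (2.63) and Rbp2 (-1.12), but not called without wild-type replicate 2 (0.0898) or at a minimum mean of 5 (0.169). Tuft cell markers were higher (12 of 13 positive, median 0.30, adjusted p = 0.0228), with Avil (0.50), Gnat3 (0.50) and Matk (0.31), though not called at a minimum mean of 5 (0.201), with the position covariate (0.496) or without wild-type replicate 3 (0.727), which alone lay low at -0.56 from the wild-type mean. Enteric glia and neuron markers were higher (10 of 10, median 0.24, adjusted p = 0.0242), with Stmn2 (0.45), Snap25 (0.39), Tac1 (0.42) and Vip (0.11), but not without knock-out replicate 1 (0.126) or wild-type replicate 3 (0.305) or at a minimum mean of 5 (0.113), and with the position covariate the list was called lower (median -0.24, 0.0440). That last call rests largely on wild-type replicate 2, where the list lay at 0.43 from the wild-type mean. Endothelial markers were lower (6 of 6, median -0.43, adjusted p = 0.0404), with Plvap (-0.37), Pecam1 (-0.55), and the lymphatic genes Ccl21a (-0.76) and Mmrn1 (-0.46), but not called when any 1 knock-out library (0.0719, 0.102 and 0.0553) or wild-type replicate 1 (0.133) was left out, with other pseudocounts (0.0560 and 0.0598) or with the position covariate (0.852).

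Mesenchymal and matrix genes were higher (12 of 17 positive, median 0.19, adjusted p = 0.0222), with Thbs1 (0.76), Sparc (0.48), Vim (0.41) and Acta2 (0.53), but not without knock-out replicate 2 (0.171) or wild-type replicate 3 (0.137) or with the position covariate (0.950). Epithelial junction genes were higher (21 of 29 positive, median 0.10, adjusted p = 0.0280), with Cldn4 (0.75) and Vil1 (0.30) positive and Muc1 (-1.86) and Ocln (-0.36) negative, but not without knock-out replicate 2 (0.449) or wild-type replicate 3 (0.137), with no minimum mean (0.0547) or with the position covariate (median 0.0114, 0.844). Xenobiotic and NRF2 targets were higher (12 of 17 positive, median 0.28, adjusted p = 0.0242), with Ugt1a6a (1.15), Nqo1 (0.71), Taldo1 (0.52) and Gstm1 (-0.40), but not without knock-out replicate 2 (0.163), with no minimum mean (0.0813) or with the position covariate (median 0.0507, 0.0747). TGF-beta targets were higher (12 of 15 positive, median 0.13, adjusted p = 0.0366), with Ctgf (0.49), Tgfbi (0.87), Bhlhe40 (0.26) and Id1 (-0.41), but not without knock-out replicate 3 (0.0664) or wild-type replicate 3 (0.0806), with no minimum mean (0.0563) or one of 5 (0.155), or with the position covariate (0.537). Mitochondrial translation genes were lower (28 of 34 negative, median -0.09, adjusted p = 0.0346), with Mrps35 (-0.25), Mrpl9 (-0.27), Mrpl13 (-0.17) and Mrpl15 (-0.14), but not without knock-out replicate 2 (0.206), wild-type replicate 2 (0.351) or wild-type replicate 3 (0.0759).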
